A study of Oryza sativa Indica Group with 27 samples.

How the data were processed

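Whole 7-day-old seedlings of the indica rice cultivars Nonabokra, Pokkali and IR29 were kept in growth medium or in 200 mM sodium chloride, and each RNA was labelled and hybridised to an Affymetrix rice genome array. The labels give 9 groups of 3 arrays: unstressed, 3 h and 6 h of salt in each cultivar. The description of the 3 h samples speaks of drought, while their titles, characteristics and treatment give salt, and they were taken as salt. The deposited values are linear intensities made by the authors, whose notes name only the GCOS scanner software. How probes were summarised and how arrays were normalised is not stated. Quartiles of the arrays lay close together, with upper quartiles from 158 to 175 and medians from 7.09 to 7.77, so no further scaling was applied. Median log2 values spanned 0.042, under the limit of 0.2 set for rescaling.

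Values were analysed as log2(intensity + 16), which understates changes of dim transcripts. The table holds 57381 probe sets, and 187 control and reporter probe sets were left out of the tests. limma's linear model with 1 mean per group was fitted to all 27 arrays (18 residual degrees of freedom) with moderated t tests and Benjamini-Hochberg adjustment over 57194 probe sets in each comparison. A probe set passed at adjusted p under 0.05. Salt was compared with control at 3 h and 6 h in each cultivar, 6 h with 3 h, and unstressed cultivars with each other. Differences between cultivars in their salt response were tested as interactions. Of the tested probe sets, 22436 were paired with 1 gene, 95 with several and 34663 with none. Each of 17905 genes was represented by its probe set of highest mean, and 2457 of them carry an informative name. Detection calls were not used here. Control probe sets and spikes served as signs of RNA handling and labelling. Groups share the replicate numbers 1 to 3, and the labels do not say what a number marks. The residuals of arrays with the same number correlated at over 0.1 in all 3 pairs for 2 of 36 pairs of groups: Nonabokra and IR29 at 6 h (0.73, 0.42 and 0.40) and unstressed Nonabokra and Pokkali (0.47, 0.16 and 0.19). That pairing comes from the values alone.

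Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Adjustment ran over 26 lists of at least 3 genes and the 12 comparisons of groups, 312 tests, of which 81 passed and 38 also passed with an estimated correlation. The lists are abscisic acid synthesis and breakdown (2 genes, not tested), late embryogenesis abundant and dehydrin genes, salt and drought regulators, sodium and potassium transport, osmoprotectant synthesis, protein phosphatases 2C, heat shock proteins, heat shock factors, NAC, AP2/ERF and WRKY factors, TIFY/JAZ repressors, jasmonate synthesis, glutathione S-transferases, class III peroxidases, antioxidant enzymes, aquaporins, expansins, cellulose synthases, lipid transfer proteins, photosynthesis, cytosolic ribosomal proteins, core histones, tubulins, circadian clock, root markers and seed storage. Some lists share members. DREB1A, DREB1B, DREB1C, DREB2A and DREB2B are both regulators and AP2/ERF factors, and NAC5 and NAC6 both regulators and NAC factors. Single stress genes (salT, ACO1, ACS2, NIA1 and hsp101) were read singly. Spellings under which list members were looked up were written once the gene tables had been seen and while the values had not. Some lists matched only part of the members fixed for them.

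Genes to be named were set by rule: for each cultivar the 8 largest rises and 8 largest falls at 6 h, and 4 and 4 at 3 h, whose salt arrays all lay beyond the control arrays. To these came the 10 and 10 genes with the largest shared change in all 3 cultivars, and the 6 and 6 largest unstressed differences of both tolerant cultivars with 3 and 3 of each alone. The rule ends with the 5 and 5 largest response differences, the 4 and 4 largest changes from 3 h to 6 h, up to 4 passing members of each list, and list members fixed singly. Groups, comparisons, lists, the rule and most alternatives were fixed before the data were examined. Alternatives were a trended and a robust spread, a fit to the compared groups alone, a filter on the dimmest 40%, quantile normalization, median centring, pseudocounts of 1 and 64, named genes only, a threshold of 0.01, a replicate block, array weights and leaving out each array. For lists they were an estimated correlation, fry, a replicate block and the mean of all probe sets of a gene. Alternatives added later leave out 2 arrays that differ most from their groups, leave out each array for named genes, and use the default estimate of array weights. Array weights were planned, but their gene-by-gene estimate was chosen later, because the default did not converge.

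The procedure was tested on simulated data with the size and spread of this series. Changed probe sets were drawn from the brightest ones, so recovery of dim ones was not tested. Noise was independent, so an offset shared by the arrays of a group was not simulated. With 50 probe sets changed 2-fold in Nonabokra at 6 h, 46 passed, as did 41 at 1.5-fold and 50 at 4-fold. For a difference in response 39, 24 and 50 passed, with 6 false calls among 57194. Work was done in R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.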

Results

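Transcript levels were measured in whole 7-day-old seedlings of 3 indica rice cultivars on 27 single-colour oligonucleotide arrays. Nonabokra and Pokkali are salt-tolerant cultivars and IR29 is salt-susceptible, so the comparisons ask which transcripts salt changes and where the tolerant cultivars differ from the susceptible one, before salt and in their response. Seedlings were placed in 200 mM sodium chloride for 3 h or 6 h, or were kept in growth medium for 6 h as unstressed controls, which gave 9 groups of 3 arrays. The median intensity of an array lay between 7.09 and 7.77, and between 28.8% and 29.7% of its 57194 tested probe sets lay above an intensity of 100. The number of arrays limits the precision, and the median residual SD was 0.10 on the log2 scale among the brighter probe sets. Changes below are differences of log2(intensity + 16) ± limma's standard error, so the size of a change from a level near the array median depends on the added 16. Intensities are means ± SD, and each group has n = 3 arrays.

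Several signs of RNA handling moved with the groups. The poly-A spike transcripts, which are added to the RNA before labelling, changed by -0.59 ± 0.39 (SE) on the log2 scale in Nonabokra, -0.51 ± 0.16 in Pokkali and -0.40 ± 0.18 in IR29 at 3 h, and by -1.96 ± 0.49, -1.39 ± 0.10 and -1.33 ± 0.34 at 6 h (permutation p = 1e-05 for the time point, permuted within cultivars, the smallest value possible). The control probe set for 18S rRNA had a mean level of 2361 in unstressed IR29, 21.8 at 3 h and 73.0 at 6 h, and the hybridisation spikes were higher by 0.59 ± 0.20 in IR29 at 6 h. The ratio of the actin 5′ to the 3′ probe sets changed by -0.82 ± 0.32 on the log2 scale at 3 h and -0.59 ± 0.12 at 6 h in Pokkali. In IR29 at 3 h it changed by -0.79 ± 0.36. The other rice transcripts with such a ratio changed little in Pokkali at 3 h: gapdh by 0.02 ± 0.10, cyclophilin by 0.01 ± 0.11 and ubiquitin by 0.05 ± 0.11. The ratio for the added dap spike changed by -1.27 ± 0.60 there, so the actin ratio alone does not show a difference in RNA quality. Replicate 1 of Nonabokra at 6 h correlated across probe sets with its group at r = 0.9965 and 0.9964, against 0.9992 for the other pair, and replicate 1 of IR29 at 6 h at 0.9957 and 0.9959, against 0.9990. Replicate 3 of the unstressed Nonabokra correlated at 0.9957 and 0.9971, against 0.9984, and without it the Nonabokra counts given below were 15774 at 3 h and 12424 at 6 h. Probe sets are not independent replicates.

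In Nonabokra, salt raised transcripts of late embryogenesis abundant proteins, which accumulate in drying seeds and stressed tissue. RAB16D rose from an intensity of 67.4 ± 8.72 in unstressed seedlings to 6817 ± 119 at 3 h and 3407 ± 185 at 6 h. Its change was 6.36 ± 0.06 and 5.36 ± 0.06 (adjusted p = 7.3e-23 and 1.0e-21). HOX24, a homeodomain-leucine zipper factor, rose from an intensity of 5.81 ± 0.0430 to 4524 ± 268 at 3 h and 512 at 6 h. The AP2-domain factors DREB1A and DREB1B rose later, from 2.25 and 0.48 at 3 h to 4.73 and 4.39 at 6 h. AMY1.1, an alpha-amylase, fell from 3440.0 ± 165 to 176 ± 29.7 and then 5.83 ± 0.0991. CYP71Z7, a cytochrome P450 of diterpenoid synthesis, changed by -4.25 and -4.09.

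All 8 late embryogenesis abundant and dehydrin genes rose at 3 h, with a median of 4.24 (adjusted p = 1.8e-08), and all 8 at 6 h, with a median of 3.60 (adjusted p = 4.2e-10). Both measured genes of abscisic acid breakdown rose at 6 h, ABA8OX1 by 2.67 and ABA8OX2 by 2.30, a list too short for a list test. Among the salt and drought regulators at 6 h, 6 of 9 members rose, none fell and 3 did not pass, with a median of 1.00 (adjusted p = 0.00092). At 3 h the regulators had 5 higher and 0 lower (adjusted p = 0.016, or adjusted p = 0.052 with an estimated correlation). Among the protein phosphatases 2C at 3 h, 29 of 56 members rose, 11 fell and 16 did not pass, with a median of 0.21 (adjusted p = 0.012, or adjusted p = 0.054 with an estimated correlation). PP2C59 rose by 4.96 and PP2C68 by 4.29, and at 6 h the phosphatases had 23 higher and 14 lower (adjusted p = 0.038, or adjusted p = 0.11 with an estimated correlation). Among the heat shock proteins at 3 h, 13 of 23 members rose, 3 fell and 7 did not pass, with a median of 0.31 (adjusted p = 0.0025, or adjusted p = 0.13 with an estimated correlation). HSP18.6 rose by 4.75, and at 6 h these proteins had 13 higher and 3 lower (adjusted p = 0.014, or adjusted p = 0.23 with an estimated correlation). The heat shock factors had 10 higher and 3 lower of 18 at 3 h (adjusted p = 0.046, or adjusted p = 0.15 with an estimated correlation). Adjusted over the list alone, the phosphatases at 3 h had 30 higher and 14 lower, the phosphatases at 6 h had 24 higher and 15 lower and the heat shock proteins at 6 h had 13 higher and 4 lower. In the same way, the heat shock factors had 12 higher and 4 lower, and the other counts of this paragraph were the same.

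Ribosomal proteins, core histones and tubulins were lower in Nonabokra at 3 h. Among the cytosolic ribosomal proteins, none of 24 members rose, 22 fell and 2 did not pass, with a median of -0.36 (adjusted p = 3.9e-05). At 6 h 4 of the 24 were lower, among them RPL27 at -0.96 and RPL18 at -0.75 (adjusted p = 0.44). All 6 core histones fell at 3 h, with a median of -0.85 (adjusted p = 0.0093, or adjusted p = 0.18 with an estimated correlation). The 6 measured members are H2B.5, H2B.6, H2B.7, H2B.10, H2B.11 and CenH3, so here and below this list speaks mainly of H2B genes. Of 10 tubulins, 9 fell at 3 h (adjusted p = 0.0018) and 9 at 6 h (adjusted p = 0.0029), with TUB1 at -1.32 and -0.88. Among the expansins at 6 h, 11 of 29 members rose, none fell and 18 did not pass, with a median of 0.06 (adjusted p = 0.018, or adjusted p = 0.12 with an estimated correlation). LTP-2, a lipid transfer protein, rose by 5.59 ± 0.12 at 6 h, in a list with 4 higher and 1 lower of 5 (adjusted p = 0.040, or adjusted p = 0.14 with an estimated correlation). The AP2/ERF factors had 6 higher and 0 lower of 12 at 6 h (adjusted p = 0.034, or adjusted p = 0.23 with an estimated correlation). When adjusted over the list alone, the ribosomal proteins had 0 higher and 23 lower, and the other counts of this paragraph were the same. The test passed 16003 probe sets at 3 h (7458 higher and 8545 lower) and 12804 at 6 h (5848 and 6956). Changes of 2-fold or more were 2071 higher and 1879 lower at 3 h, and 1035 and 1161 at 6 h.

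In Pokkali, the late embryogenesis abundant transcripts stood high before salt, and other genes led the response. RAB16D had an intensity of 6764 ± 394 unstressed, 7841 ± 372 at 3 h and 3558 ± 106 at 6 h, with a change of -0.92 ± 0.06 at 6 h (adjusted p = 8.3e-10). HOX24 rose from 67.0 ± 7.57 to 3441 ± 292 at 6 h, a change of 5.38 ± 0.09 (adjusted p = 4.9e-19). ICL, isocitrate lyase of the glyoxylate cycle, rose by 5.09 ± 0.07 at 3 h and 4.93 ± 0.07 at 6 h. NSHB2, a non-symbiotic haemoglobin, rose by 5.74 ± 0.11 and 3.81 ± 0.11, and DREB1A by 2.91 and 4.17. Among the genes lower at 6 h were ADC2 at -2.70, CIPK5, a protein kinase that binds calcium sensors, at -2.61, and NIP2-2, a channel protein of the aquaporin family, at -2.37.

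All 8 late embryogenesis abundant and dehydrin genes rose in Pokkali at 3 h, 3 of them 2-fold or more, with a median of 0.85 (adjusted p = 0.00027). At 6 h 5 of 8 members rose, 2 fell and 1 did not pass, with RAB21 at 1.54 and RAB16C at -0.88 (adjusted p = 0.33). Among the salt and drought regulators at 6 h, 6 of 9 members rose, none fell and 3 did not pass, with a median of 1.40 (adjusted p = 0.00012). NAC6 rose by 2.44 and DREB2A by 1.80, and at 3 h the regulators had 6 higher and 0 lower (adjusted p = 0.0042). The AP2/ERF factors had 6 higher and 1 lower of 12 at 6 h (adjusted p = 0.0057, or adjusted p = 0.12 with an estimated correlation) and 6 higher and 0 lower at 3 h (adjusted p = 0.025, or adjusted p = 0.20 with an estimated correlation). Regulators and AP2/ERF factors share DREB1A, DREB1B, DREB1C, DREB2A and DREB2B, so their results overlap. Among the lipid transfer proteins at 6 h, 4 of 5 members rose, none fell and 1 did not pass, with a median of 0.32 (adjusted p = 0.0041). LTP-2 rose by 5.13 ± 0.12, and at 3 h the list had 3 higher and 0 lower (adjusted p = 0.026, or adjusted p = 0.12 with an estimated correlation). ABA8OX1 rose by 2.62 at 3 h and 3.16 at 6 h, and ABA8OX2 rose by 1.55 at 3 h and did not pass at 6 h. In counts adjusted over the list alone, the regulators at 6 h had 7 higher and 0 lower and the AP2/ERF factors at 3 h had 7 higher and 0 lower, and the other counts of this paragraph were the same.

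Among the cytosolic ribosomal proteins of Pokkali at 3 h, none of 24 members rose, 20 fell and 4 did not pass, with a median of -0.23 (adjusted p = 0.00076, or adjusted p = 0.064 with an estimated correlation). All 6 core histones were lower at 3 h (adjusted p = 0.0020, or adjusted p = 0.12 with an estimated correlation), where H2B.10 fell by 1.96. All 6 were lower at 6 h, with a median of -0.37 (adjusted p = 0.031, or adjusted p = 0.26 with an estimated correlation). Of 10 tubulins, 9 fell at 3 h (adjusted p = 0.0010) and 7 at 6 h (adjusted p = 0.0054), with TUB6 at -1.41 and -1.28. Among the aquaporins at 6 h, 2 of 25 members rose, 13 fell and 10 did not pass, with a median of -0.18 (adjusted p = 0.0054, or adjusted p = 0.089 with an estimated correlation). TIP2-1 was at -1.87, whereas TIP3-1 rose by 4.01. Adjusted over the list alone, the aquaporins had 2 higher and 16 lower, and the other counts of this paragraph were the same. The test passed 14427 probe sets at 3 h (6772 higher, 7655 lower) and 12729 at 6 h (5785 higher, 6944 lower). At 6 h median centring gave 6059 higher and 5685 lower, and array weights 7035 higher and 19108 lower. Changes of 2-fold or more numbered 1536 higher and 1578 lower at 3 h, and 1191 and 655 at 6 h.

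In IR29, AMY1.1 and EP3A rose at 3 h and were at low levels by 6 h. AMY1.1 went from 162 ± 23.4 to 24130.0 ± 1481 at 3 h and 6.61 ± 0.831 at 6 h, changes of 7.09 ± 0.10 and -2.97 ± 0.10 (adjusted p = 2.5e-20 and 1.8e-14). EP3A went from 5.51 to 1037 and 5.24. PBZ1, a pathogenesis-related protein, went from 944 ± 29.6 to 22790.0 ± 1257 and 5814 ± 280.5. HOX24 rose by 5.55 ± 0.09 and 6.39 ± 0.09, and RAB16D by 3.28 ± 0.06 and 4.33 ± 0.06, from an intensity of 64.3 to 1598 at 6 h. NIP2-1 and Lsi2, which carry silicon in roots, changed by -4.41 and -3.61 at 3 h. DREB1B fell, with -2.66 at 3 h and -2.50 at 6 h.

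All 8 late embryogenesis abundant and dehydrin genes rose in IR29 at 3 h, with a median of 2.54 (adjusted p = 8.4e-08), and all 8 at 6 h, with a median of 2.90 (adjusted p = 6.2e-11). Among the heat shock factors at 6 h, 12 of 18 members rose, none fell and 6 did not pass, with a median of 0.56 (adjusted p = 7.7e-05). HSFA6B rose by 2.00, and at 3 h these factors had 14 higher and 1 lower (adjusted p = 0.0012). Among the heat shock proteins at 3 h, 16 of 23 members rose, 3 fell and 4 did not pass, with a median of 0.34 (adjusted p = 0.026, or adjusted p = 0.26 with an estimated correlation). Among the protein phosphatases 2C at 3 h, 29 of 56 members rose, 9 fell and 18 did not pass, with a median of 0.25 (adjusted p = 0.0058). At 6 h the phosphatases had 26 higher and 11 lower (adjusted p = 0.012, or adjusted p = 0.054 with an estimated correlation), with PP2C59 at 4.76 and PP2C68 at 3.57. The salt and drought regulators split, with 4 higher and 5 lower at 3 h (adjusted p = 0.98) and 4 higher and 3 lower at 6 h (adjusted p = 0.54), where BZIP23 was at 2.23. At 3 h their median (-0.10) and mean (0.12) differed in sign. ABA8OX1 was at -0.49 at 3 h and did not pass at 6 h, while ABA8OX2 rose by 1.83 and 1.09. When adjusted over the list alone, all counts of this paragraph were the same.

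All 4 root markers fell in IR29 at 3 h, with a median of -3.12 (adjusted p = 0.00027), IRT1 at -2.62 and CASP1 at -0.82. At 6 h 3 of the 4 were lower (adjusted p = 0.0093, or adjusted p = 0.064 with an estimated correlation). At 3 h the same markers had 2 higher and 2 lower in Nonabokra (adjusted p = 0.71) and 1 higher and 2 lower in Pokkali (adjusted p = 0.33). Among the cytosolic ribosomal proteins of IR29 at 3 h, none of 24 members rose, 22 fell and 2 did not pass, with a median of -0.39 (adjusted p = 3.2e-07). At 6 h 17 of the 24 were lower and 1 higher (adjusted p = 0.0010, or adjusted p = 0.072 with an estimated correlation). All 6 core histones were lower at 3 h, with a median of -0.58 (adjusted p = 0.0041, or adjusted p = 0.13 with an estimated correlation), as were 8 of 10 tubulins (adjusted p = 0.0020). All 3 class III peroxidases fell at 6 h, PRX112 to a change of -1.17 (adjusted p = 0.0054). In counts adjusted over the list alone, the ribosomal proteins at 6 h had 2 higher and 17 lower, and the other counts of this paragraph were the same.

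The IR29 tests passed 36580 probe sets at 3 h (8990 higher, 27590 lower) and 30525 at 6 h (6858 higher, 23667 lower). Changes of 2-fold or more numbered 1605 higher and 903 lower at 3 h, and 1027 and 508 at 6 h. Among all passing probe sets the median absolute change was 0.039 and 0.025, against 0.59 and 0.50 in Nonabokra. The reporter control probe sets shifted by -0.022 ± 0.0058 (SE) at 3 h and -0.013 ± 0.0083 at 6 h. The array medians shifted by -0.023 ± 0.0059 and -0.016 ± 0.0080. Of the passing probe sets 43.8% and 46.6% were among the dimmest 40%, and the split depended on the scaling: median centring gave 25667 higher and 8653 lower at 3 h and 15312 higher and 6910 lower at 6 h, quantile normalization 8209 higher and 12026 lower and 6053 higher and 9172 lower. Without replicate 1 of the IR29 controls the 6 h count was 18127, and without replicate 2 of the 6 h arrays 18474.

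**Figure D1:**
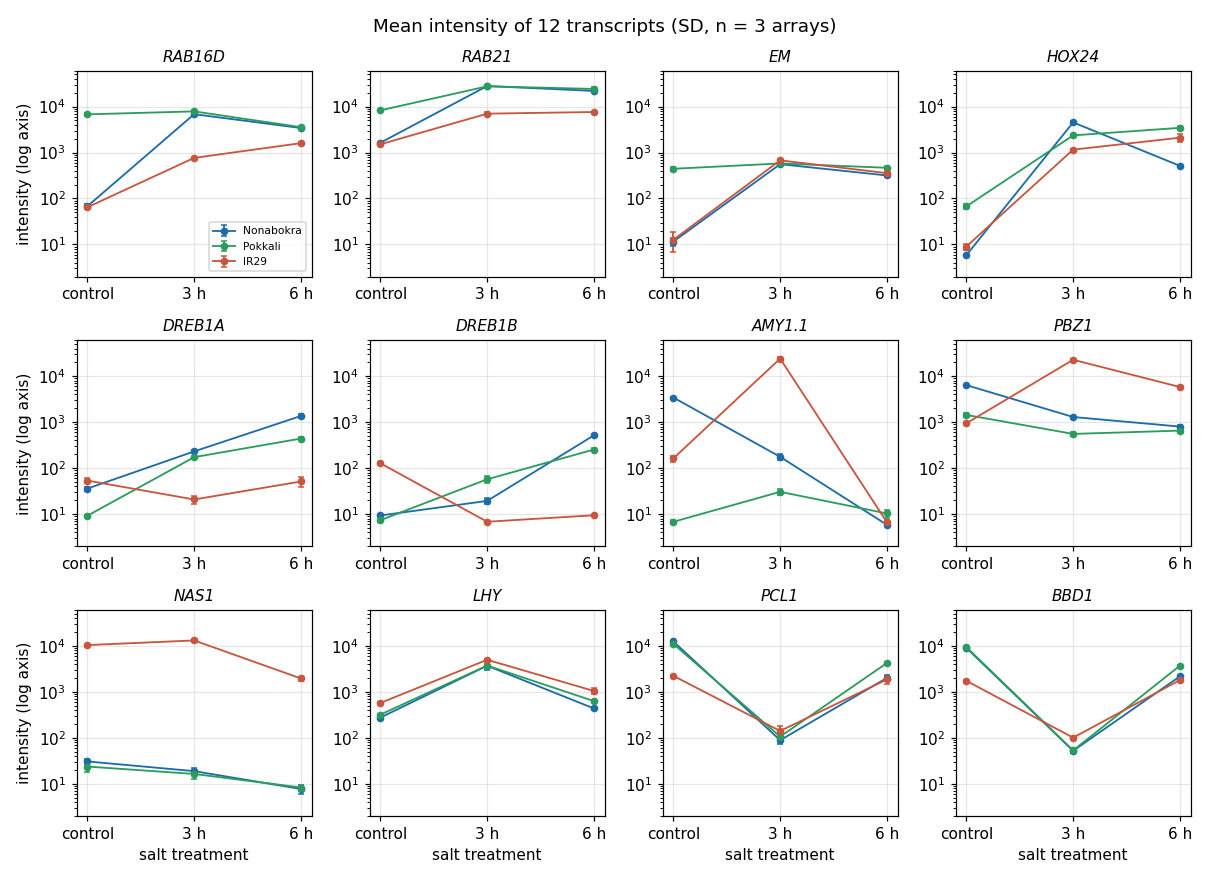
Mean intensity (log axis, SD bars, n = 3 arrays) of 12 transcripts in unstressed, 3 h and 6 h seedlings of the 3 cultivars. RAB16D stands at 6764 in unstressed Pokkali against 67.4 in Nonabokra and 64.3 in IR29, and AMY1.1 reaches 24130.0 in IR29 at 3 h.

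Part of the response was shared by all 3 cultivars. HOX24, PP2C59, SWEET15 (a sugar transporter), TIP3-1 (a tonoplast aquaporin) and ICL rose at 6 h in each of them. In Nonabokra, Pokkali and IR29, HOX24 was at 4.60, 5.38 and 6.39, from unstressed intensities of 5.81, 67.0 and 8.98, and TIP3-1 at 4.41, 4.01 and 2.66. CRSH2 (-4.06, -2.83 and -1.24), NIP2-2 (-2.23, -2.37 and -1.49), the potassium channel AKT1 (-1.12, -1.14 and -1.94) and the allene oxide synthase AOS4 (-1.13, -1.55 and -2.55) fell in each. Of the named genes, 538 passed in the same direction in all 3 cultivars at 6 h, 300 of them higher and 238 lower. At 3 h, 3925 probe sets were higher and 3823 lower in all 3 cultivars, where independent lists would share 139 and 552. At 6 h the counts were 2465 and 2042 against 70.9 and 349. Counting changes of 2-fold or more gave 655 and 383 at 3 h and 338 and 78 at 6 h. The figure for independent lists depends on the dim probe sets. Without the dimmest ones the counts for all 3 cultivars at 3 h were 4126 and 3961 against 412 and 612. At 6 h they were 2601 and 2141 against 210 and 272. Falls that IR29 shared at 3 h with Nonabokra and with Pokkali lay nearer to that figure. They were 4859 and 4361 against 4122 and 3693. Without the dimmest probe sets they were 4918 and 4467 against 2626 and 2388. Changes of Nonabokra and Pokkali correlated across probe sets, which are not independent, at r = 0.780 at 3 h and 0.613 at 6 h. Nonabokra and IR29 gave r = 0.651 and 0.544, and Pokkali and IR29 0.611 and 0.518.

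**Figure D2:**
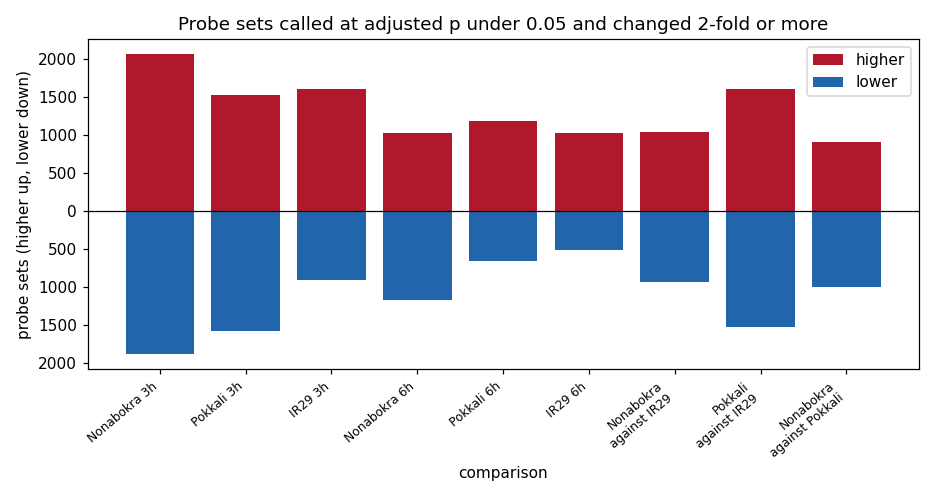
Number of probe sets at adjusted p under 0.05 that were 2-fold or more higher (upward bars) or lower (downward bars) in each salt comparison and between unstressed cultivars. Nonabokra at 3 h has 2071 higher and 1879 lower, and IR29 at 6 h 1027 and 508.

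The tests of 12 other lists passed in none of the 6 salt comparisons. Counts are given as higher and lower at 6 h in Nonabokra, Pokkali and IR29 in turn. The sodium and potassium transport genes had 5 and 8, 6 and 8, and 13 and 6 of 28, with KCO2 at 1.38 in Pokkali and HAK17 at -2.34 in Nonabokra. Most of the 28 are HAK genes, and HKT1;5 is the only HKT gene among them. SOS1, NHX1, HKT1;1 and HKT2;1 had been fixed for the list but are not among its measured members, so it does not speak to them. The osmoprotectant synthesis genes had 4 and 4, 4 and 3, and 4 and 5 of 10, and P5CS2 of proline synthesis rose by 1.63, 0.79 and 1.41. The NAC factors had 4 and 0, 4 and 1, and 4 and 1 of 8, with NAC6 at 1.69, 2.44 and 1.58. Jasmonate synthesis genes had 2 and 9, 5 and 7, and 7 and 7 of 18, with AOS3 at 1.15, 2.21 and 2.63. The TIFY/JAZ repressors had 5 and 2, 7 and 5, and 4 and 8 of 17, with JAZ13 at 2.55, 3.31 and -0.61. The WRKY factors had 2 and 2, 3 and 0, and 2 and 1 of 6. Antioxidant enzymes had 8 and 2, 7 and 3, and 9 and 1 of 14, with the catalase CAT-B at 0.99, 0.64 and 0.58. Glutathione S-transferases had 1 and 4, 2 and 3, and 2 and 1 of 6. Cellulose synthases had 6 and 12, 7 and 9, and 8 and 4 of 29. Photosynthesis genes of the shoot had 1 and 5, 1 and 4, and 2 and 1 of 9. Seed storage genes had 0 and 1, 0 and 1, and 0 and 7 of 10. Circadian clock genes had 1 and 1, 1 and 1, and 1 and 1 of 6. Adjusted over the list alone, transport genes had 6 and 11 in Nonabokra, 8 and 8 in Pokkali and 14 and 6 in IR29, osmoprotectant genes had 4 and 4 in Pokkali, and jasmonate genes had 5 and 10 in Pokkali. In the same way, TIFY/JAZ repressors had 6 and 4 in Nonabokra and 8 and 5 in Pokkali, WRKY factors had 3 and 1 in Pokkali, and antioxidant enzymes had 8 and 3 in Nonabokra, 8 and 4 in Pokkali and 9 and 2 in IR29. In the same way, cellulose synthases had 7 and 12 in Nonabokra and 7 and 11 in Pokkali, photosynthesis genes had 2 and 0 in IR29, and clock genes had 1 and 3 in Nonabokra and 1 and 2 in Pokkali, and the other list counts of this paragraph were the same. Among single stress genes, salT rose by 2.17 in Nonabokra, 2.21 in Pokkali and 0.39 in IR29, and ACO1 of ethylene synthesis by 1.37, 0.80 and 0.88. The heat shock gene hsp101 rose by 1.25 in Nonabokra and 1.08 in IR29, NIA1 was at -0.28 in Nonabokra and 1.16 in Pokkali, and ACS2 rose by 0.94 in Pokkali and from an intensity of 45.2 to 122 in IR29. In the remaining cultivar hsp101, NIA1 and ACS2 did not pass.

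**Figure D3:**
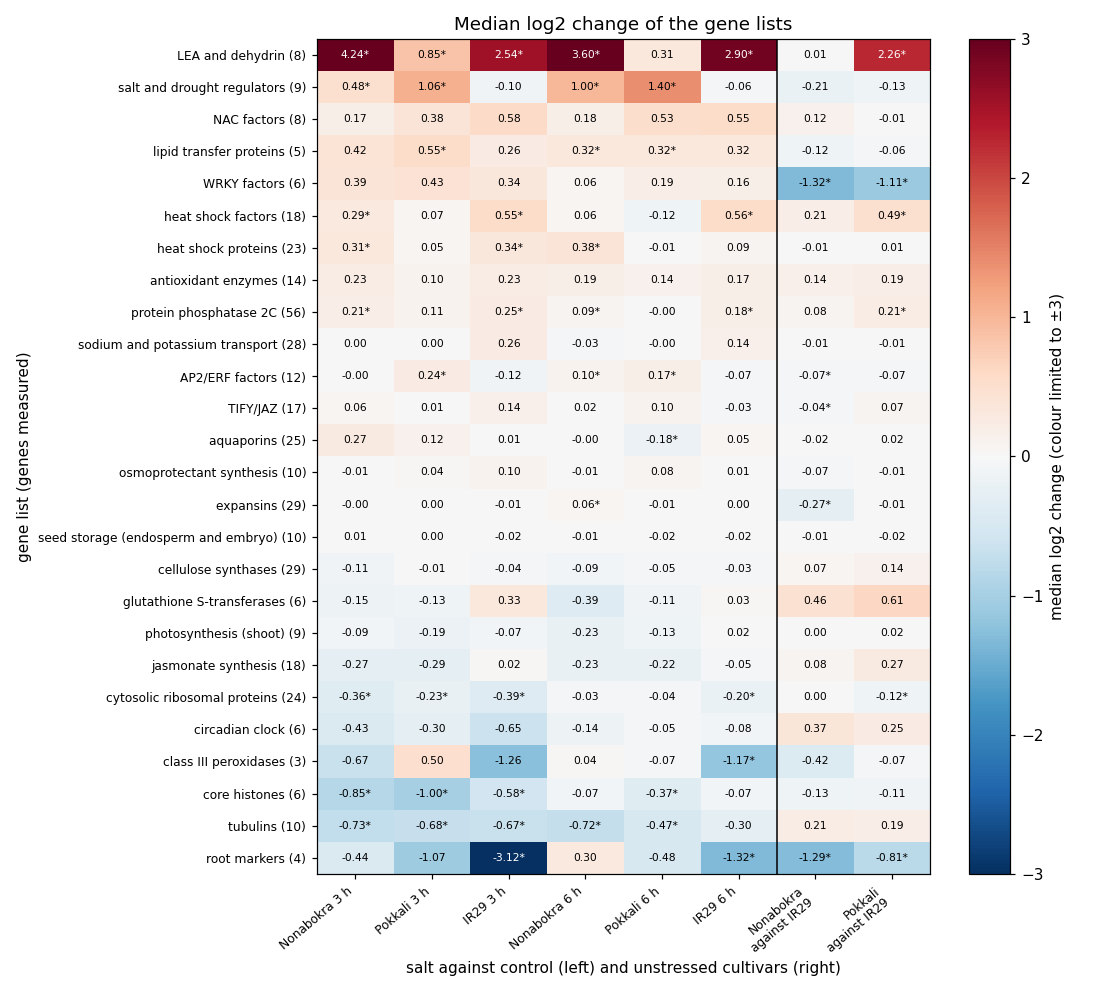
Median log2 change of each gene list (number of genes in brackets) in the 6 salt comparisons and in unstressed Nonabokra and Pokkali against IR29, with a star where the list test had an adjusted p under 0.05. The late embryogenesis abundant genes have medians of 4.24 in Nonabokra at 3 h and 2.26 in unstressed Pokkali against IR29.

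Between 3 h and 6 h, PCL1 and LHY changed in all 3 cultivars. PCL1, a clock component outside the clock list, changed by -6.91, -6.51 and -3.87 at 3 h against control in Nonabokra, Pokkali and IR29, then rose by 4.28, 5.13 and 3.60 from 3 h to 6 h. LHY, which is in the list, was at 3.66, 3.48 and 3.09 against control at 3 h and 0.63, 0.94 and 0.84 at 6 h. From 3 h to 6 h the clock list had 3 higher and 1 lower of 6 in Nonabokra (adjusted p = 0.38), 3 higher and 2 lower in Pokkali (adjusted p = 0.72) and 4 higher and 1 lower in IR29 (adjusted p = 0.066). Adjusted over the list alone, the list in IR29 had 4 higher and 2 lower, and the other counts of this paragraph were the same. The controls were kept in medium for 6 h, so the 3 h seedlings had no control of their own time. BBD1 rose by 5.01, 5.76 and 3.96 from 3 h to 6 h. DREB1B rose by 3.92 ± 0.08 in Nonabokra and 1.89 ± 0.08 in Pokkali, while in IR29 AMY1.1 changed by -10.06 ± 0.10.

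Ribosomal protein genes rose from 3 h to 6 h, 21 of 24 in Nonabokra (adjusted p = 9.3e-06), 18 in Pokkali (adjusted p = 0.00010) and 14 in IR29 (adjusted p = 9.3e-06). Of 6 core histones, 5 rose in Nonabokra (adjusted p = 0.0015, or adjusted p = 0.11 with an estimated correlation), 6 in Pokkali (adjusted p = 0.0049, or adjusted p = 0.14 with an estimated correlation) and 6 in IR29 (adjusted p = 0.00012). Of 8 late embryogenesis abundant genes, 8 fell from 3 h to 6 h in Nonabokra (adjusted p = 8.1e-06) and 6 in Pokkali (adjusted p = 0.00017). In IR29 the list had 4 higher and 1 lower (adjusted p = 0.018, or adjusted p = 0.12 with an estimated correlation). All 4 root markers rose in IR29, with a median of 1.53 (adjusted p = 9.3e-06), as did 8 of 10 tubulins (adjusted p = 0.00092). In Pokkali 16 of 25 aquaporins fell and 4 rose (adjusted p = 0.00080), with PIP2-4 at -2.66. When adjusted over the list alone, ribosomal proteins of Nonabokra had 22 higher and 2 lower, ribosomal proteins of Pokkali had 19 higher and 0 lower and ribosomal proteins of IR29 had 17 higher and 0 lower. In the same way, late embryogenesis genes of Pokkali had 0 higher and 7 lower, late embryogenesis genes of IR29 had 5 higher and 1 lower and aquaporins had 4 higher and 18 lower, and the other counts of this paragraph were the same.

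From 3 h to 6 h more of the 23 heat shock proteins were lower than higher in each cultivar, many did not pass, and no list test of them passed with an estimated correlation. In Nonabokra the list had 3 higher and 9 lower of 23 (adjusted p = 0.012, or adjusted p = 0.22 with an estimated correlation), HSP18.6 at -3.72, in Pokkali it had 1 higher and 7 lower of 23 (adjusted p = 0.036, or adjusted p = 0.29 with an estimated correlation) with a median of -0.03, and in IR29 it had 0 higher and 11 lower of 23 (adjusted p = 0.0010, or adjusted p = 0.11 with an estimated correlation). Nonabokra's heat shock factors had 2 higher and 9 lower of 18 (adjusted p = 0.026, or adjusted p = 0.12 with an estimated correlation), and its protein phosphatases 2C had 9 higher and 25 lower of 56 (adjusted p = 0.037, or adjusted p = 0.11 with an estimated correlation). Pokkali's class III peroxidases had 0 higher and 3 lower of 3 (adjusted p = 0.048, or adjusted p = 0.12 with an estimated correlation), and its salt and drought regulators had 5 higher and 0 lower of 9 (adjusted p = 0.031, or adjusted p = 0.075 with an estimated correlation). IR29's WRKY factors had 0 higher and 4 lower of 6 (adjusted p = 0.0055, or adjusted p = 0.054 with an estimated correlation), and its TIFY/JAZ repressors had 0 higher and 8 lower of 17 (adjusted p = 0.036, or adjusted p = 0.12 with an estimated correlation). In counts adjusted over the list alone, heat shock proteins of Nonabokra had 3 higher and 10 lower, heat shock proteins of IR29 had 0 higher and 13 lower and heat shock factors had 2 higher and 10 lower. In the same way, protein phosphatases 2C had 13 higher and 27 lower, salt and drought regulators had 6 higher and 0 lower and WRKY factors had 0 higher and 5 lower, and the other counts of this paragraph were the same. The poly-A spikes changed by -1.37 ± 0.33, -0.88 ± 0.14 and -0.93 ± 0.32 over the same interval in Nonabokra, Pokkali and IR29. The test passed 12060 probe sets in Nonabokra (5810 higher, 6250 lower), 16148 in Pokkali (6371 higher, 9777 lower) and 8458 in IR29 (3800 higher, 4658 lower). Without replicate 3 of Pokkali at 3 h the Pokkali count was 10549, without replicate 1 at 6 h it was 10677, median centring gave 6397 higher and 4814 lower, and array weights 7867 higher and 23825 lower. Within Nonabokra, Pokkali and IR29, the 3 h and 6 h changes correlated across probe sets at r = 0.784, 0.761 and 0.792. Shared controls alone gave 0.498 to 0.501 in simulated groups without a response, an r that arises whatever the size of the noise. The covariances were 0.191, 0.143 and 0.128, against 0.0034 in the simulated groups.

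Before salt, NAS1 differed most between IR29 and both tolerant cultivars among named genes. NAS1, a nicotianamine synthase of iron nutrition, had an intensity of 10400.0 ± 264 in IR29, 30.6 ± 3.65 in Nonabokra and 23.7 ± 5.53 in Pokkali. The log2 difference was -7.81 ± 0.10 for Nonabokra and -8.05 ± 0.10 for Pokkali (adjusted p = 1.1e-21 and 5.4e-22). NAS2 (-7.20 and -7.59) and the metal transporters YSL15 (-6.64 and -6.49), Nramp1 (-5.49 and -5.37) and IRT1 (-4.22 and -3.35) were also lower in both, and no list of metal genes was tested. The same groups differed in control probe sets, with 18S rRNA at -3.41 ± 1.09 (SE) and -1.69 ± 1.17 and 28S rRNA at -2.67 ± 0.68 and -1.74 ± 0.67 against IR29. Several genes were higher in both, among them GLT2 (3.24 and 2.55) and CIPK5 (2.34 and 3.19). RAB16D was higher in Pokkali than in IR29 by 6.40 ± 0.06, and ACO1 of ethylene synthesis by 5.27 ± 0.09.

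All 8 late embryogenesis abundant genes were higher in unstressed Pokkali than in IR29, with a median of 2.26 (adjusted p = 1.5e-07), and all 8 were lower in Nonabokra than in Pokkali (adjusted p = 6.2e-11). Nonabokra against IR29 had 0 higher and 2 lower (adjusted p = 0.52), with a median (0.01) and a mean (-0.10) that differed in sign. In Pokkali against IR29, heat shock factors had 14 higher and 0 lower of 18 (adjusted p = 0.00020), HSFC2A at 2.78. There protein phosphatases 2C had 30 higher and 12 lower of 56 (adjusted p = 0.020, or adjusted p = 0.071 with an estimated correlation), PP2C30 at 2.93, ribosomal proteins had 0 higher and 11 lower of 24 (adjusted p = 0.012, or adjusted p = 0.17 with an estimated correlation) and WRKY factors had 1 higher and 4 lower of 6 (adjusted p = 0.026, or adjusted p = 0.12 with an estimated correlation). In Nonabokra against IR29, WRKY factors had 1 higher and 5 lower of 6 (adjusted p = 0.0018), wrky38 at -2.04, and TIFY/JAZ repressors had 1 higher and 9 lower of 17 (adjusted p = 0.0049), JAZ13 at -3.02. The expansins had 4 higher and 19 lower of 29 (adjusted p = 0.0013), and the AP2/ERF factors had 1 higher and 6 lower of 12 (adjusted p = 0.048, or adjusted p = 0.26 with an estimated correlation). Root markers had 2 of 4 lower than in IR29 in Nonabokra (adjusted p = 0.0072, or adjusted p = 0.057 with an estimated correlation) and 3 in Pokkali (adjusted p = 0.031, or adjusted p = 0.12 with an estimated correlation). Adjusted over the list alone, heat shock factors had 15 higher and 0 lower, protein phosphatases 2C had 30 higher and 13 lower and root markers of Nonabokra had 0 higher and 3 lower, and the other list counts of this paragraph were the same.

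Between the tolerant cultivars, Nonabokra was lower than Pokkali in several of these groups. There heat shock factors had 0 higher and 11 lower of 18 (adjusted p = 0.0011), protein phosphatases 2C had 3 higher and 27 lower of 56 (adjusted p = 0.0020) and TIFY/JAZ repressors had 0 higher and 9 lower of 17 (adjusted p = 0.014, or adjusted p = 0.075 with an estimated correlation). The expansins had 4 higher and 14 lower of 29 (adjusted p = 0.0040, or adjusted p = 0.055 with an estimated correlation), and the ribosomal proteins had 12 higher and 0 lower of 24 (adjusted p = 0.0042, or adjusted p = 0.12 with an estimated correlation). When adjusted over the list alone, heat shock factors had 1 higher and 11 lower, protein phosphatases 2C had 5 higher and 27 lower and TIFY/JAZ repressors had 1 higher and 9 lower. In the same way, expansins had 4 higher and 15 lower and ribosomal proteins had 13 higher and 0 lower. The test passed 32034 probe sets for Nonabokra against IR29 (7659 higher, 24375 lower), 35383 for Pokkali against IR29 (9351 higher, 26032 lower) and 11081 for Nonabokra against Pokkali (5280 higher, 5801 lower). At 2-fold or more the counts were 1046 higher and 928 lower, 1607 and 1517, and 914 and 990. Both comparisons with IR29 drew 46.4% and 44.2% of their passing probe sets from the dimmest 40%, and the median absolute difference of the passing probe sets was 0.028 and 0.035. Median centring turned their splits to 21784 higher and 7107 lower in Nonabokra and 23699 higher and 7806 lower in Pokkali. Quantile normalization kept the side, with 6607 higher and 9506 lower and 8412 higher and 10007 lower. Without replicate 1 of the IR29 controls, Nonabokra against IR29 gave 21206. The 2 comparisons share the IR29 controls: 582 probe sets were 2-fold higher and 615 lower in both. Their differences correlated across probe sets at r = 0.616, against 0.501 from shared controls alone in simulated groups without a difference. A shared control gives such an r whatever the size of the noise. The covariance was 0.161, against 0.0034 in the simulated groups.

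The salt response differed between the tolerant cultivars and IR29, which was tested as an interaction. DREB1B rose from an intensity of 9.33 to 518 at 6 h in Nonabokra and from 7.37 to 254 in Pokkali, and fell from 128 to 9.42 in IR29. The response differences were 6.90 ± 0.11 and 6.03 ± 0.11 (adjusted p = 6.2e-19 and 1.2e-17), and their size depends on the 16 added to each intensity, since the low levels lie near the median of an array. DREB1A (4.80 and 4.24), DREB1G (3.40 and 4.41) and JAZ13 (3.16 and 3.92) differed in the same direction. At 3 h the response was lower than in IR29 for AMY1.1 (-11.27 ± 0.14 and -6.06 ± 0.14), PBZ1 (-6.86 and -5.92), EP3A (-8.64 and -5.60) and CPS2, a copalyl diphosphate synthase (-6.75 and -4.52). In Pokkali at 6 h it was lower than in IR29 for RAB16D (-5.25), RAB16C (-3.90) and EM (-3.64).

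GLP2, a germin-like protein, responded more than in IR29 in both cultivars at 3 h (4.08 and 3.69), HSP18.6 in Nonabokra (4.34) and NSHB2 in Pokkali (3.28). Against IR29, 14543 probe sets differed in response in Nonabokra at 3 h (8371 higher, 6172 lower) and 9286 at 6 h (4176 and 5110). Pokkali gave 26839 at 3 h (19880 and 6959) and 7323 at 6 h (3428 and 3895). Between Nonabokra and Pokkali, 7248 differed at 3 h (3865 and 3383) and 7821 at 6 h (3292 and 4529). At 2-fold or more, 2131 and 1605 differed for Nonabokra against IR29 at 3 h and 6 h, and 2062 and 1482 for Pokkali. Nonabokra against Pokkali had 1452 and 1424. At 3 h median centring turned the split to 4562 higher and 9383 lower for Nonabokra and 5310 higher and 19372 lower for Pokkali, and quantile normalization to 6983 higher and 5330 lower for Pokkali. At 6 h the split of Nonabokra against IR29 also changed side, to 8014 higher and 5470 lower without replicate 1 of Nonabokra and of IR29 at 6 h, 11897 higher and 6285 lower with array weights and 4635 higher and 4409 lower with quantile normalization. Array weights gave 5836 higher and 4729 lower for Pokkali at 6 h. Without replicate 1 of IR29 at 6 h, the Nonabokra count at 6 h was 16030.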

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

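The tests of a labelling difference, a processing batch, time of day, a sequence variant, seed remnants and a fungus, the regroupings that remove the standing cultivar difference, and the count of regroupings that part all pairs, were chosen after the result was seen, while the plain regroupings and the test for stressed controls were not.

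The salt response differed between cultivars by an interaction test. Against IR29, 14543 probe sets differed in Nonabokra at 3 h and 9286 at 6 h, and 26839 and 7323 in Pokkali. Nonabokra differed from Pokkali for 7248 at 3 h and 7821 at 6 h, of which 1452 and 1424 by 2-fold or more. The largest differences of Nonabokra against IR29 at 3 h were HSP18.6 4.34, GLP2 4.08, PLP2 3.76, GLN1-3 3.44 and LTP-2 3.37, and CPS2 -6.75, PBZ1 -6.86, CYP71Z7 -7.88, EP3A -8.64 and AMY1.1 -11.27. At 6 h they were DREB1B 6.90, DREB1A 4.80, DREB1G 3.40, JAZ13 3.16 and YSL15 3.16, and CPS2 -3.33, CYP99A2 -4.12, AMY1.1 -4.34, PBZ1 -5.58 and CYP71Z7 -5.90. For Pokkali against IR29 at 3 h they were DREB1B 4.29, DREB1A 3.83, GLP2 3.69, CDKE-1 3.33 and NSHB2 3.28, and CPS2 -4.52, CYP71Z7 -4.94, EP3A -5.60, PBZ1 -5.92 and AMY1.1 -6.06. At 6 h they were DREB1B 6.03, DREB1G 4.41, DREB1A 4.24, CDKE-1 3.97 and JAZ13 3.92, and EM -3.64, PBZ1 -3.71, RAB16C -3.90, CIPK5 -4.26 and RAB16D -5.25.

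Regrouping the 12 arrays of each response difference gave as many passing probe sets or more, the real grouping included, in 7 of 100 (30036) for Nonabokra against IR29 at 3 h and 8 of 100 (33556) at 6 h, with the highest other count in brackets. Pokkali against IR29 gave 1 of 100 (26290) at 3 h and 13 of 100 (39502) at 6 h, and Nonabokra against Pokkali 2 of 100 (12986) and 2 of 100 (13213). By this count the share was under 0.05 for Pokkali against IR29 at 3 h and for Nonabokra against Pokkali at both times, and not for the other 3. For the 2 comparisons with IR29 at 6 h the highest of these counts are several times the real ones, which points to a structure of the samples: the regroupings mix cultivars, and so carry the standing difference between cultivars into the interaction. With that difference removed from each cultivar, the counts were 1 of 100 (3559) and 1 of 100 (5051) for Nonabokra against IR29, 1 of 100 (12615) and 3 of 100 (9447) for Pokkali against IR29, and 1 of 100 (1641) and 1 of 100 (2257) for Nonabokra against Pokkali. By this second count, chosen after the first had been seen, the share was under 0.05 for all 6. For Pokkali against IR29 at 6 h other regroupings exceeded the real count by both counts, so chance is not excluded there. For Pokkali against IR29 at 3 h the plain count passed by a narrow margin, 26839 against 26290. Of those 26839 probe sets 44.8% were among the dimmest, and their median absolute difference was 0.037. Without the dimmest probe sets 11788 passed, and with quantile normalization 12313. The regroupings were not repeated under those settings. Arrays of the same number are paired by their values in Nonabokra and IR29 at 6 h and in unstressed Nonabokra and Pokkali. Among the regroupings that, like the real one, part all 3 such pairs, the plain counts were 4 of 44 (33556) for Nonabokra against IR29 at 6 h, and 2 of 42 (12986) and 2 of 42 (13213) for Nonabokra against Pokkali at 3 h and 6 h. With the standing difference removed they were 1 of 44 (1365), 1 of 42 (1641) and 1 of 42 (2257), and regroupings that part fewer pairs reached 5051, 1412 and 1535.

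Control probe sets outside the main measurement also moved with a group. The probe sets for 25S rRNA changed by 2.99 in Nonabokra at 3 h and those for 5.8S rRNA by 1.11 in Nonabokra at 6 h, in each case with all salt arrays above all control arrays.

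The first pattern is the response shared by the 3 cultivars at 3 h. A labelling difference that the poly-A spikes follow could be read from the arrays inside groups, where lower spikes went with more of the shared response (r = -0.882, permutation p = 0.0031), but the slope there gives at most 0.950% of the shared change of 4.62 in Nonabokra, 3.95 in Pokkali and 3.43 in IR29, which argues against it as the cause. A first rule would have counted that p under 0.05 for the labelling difference, and it was replaced by the share of the change once the p had been seen. Time of day would have left little of the change at 6 h, when the plants match the controls in hours, and the lowest median ratio of the 6 h to the 3 h change was 0.569, which argues against it for the shared probe sets as a set, not for single clock genes. The labels name no processing batch, and one that went with the time points, between which the spikes changed by -0.50 on average at 3 h, cannot be told apart from salt, because each group would lie in 1 batch, so a response to salt stays a hypothesis.

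The second pattern is the high level of late embryogenesis abundant transcripts in unstressed Pokkali. If its control plants had already been under salt stress as strong as the treatment, probe sets that salt raised in Nonabokra at 6 h would have risen little in Pokkali, but of 1035 such probe sets 854 rose and 34 fell in Pokkali, and the ratio of the medians was 0.775, which argues against it. The same probe sets were higher in unstressed Pokkali than in IR29 by a median of 0.23 (random lists 0.05 to 0.11), and a weaker stress of the controls was not tested. A sequence variant under the probes would leave the same difference from IR29 under salt, but the response difference of the list at 6 h had a median of -2.26 with 8 of 8 members lower. A candidate explanation is a standing difference of the cultivar in these genes, as a hypothesis found and tested on the same data.

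The third pattern is the peak of AMY1.1, EP3A, CPS2, CYP71Z7 and CYP99A2 in IR29 at 3 h. Seed remnants rich in storage transcripts are argued against by the 10 seed storage genes, of which 0 rose 2-fold and whose median change was -0.022. Rice blast fungus on the seedlings is argued against by 10 probe sets for that fungus, of which 0 rose 2-fold, the highest change being -0.0041 and the highest group mean 8.94. The storage genes cannot speak to seed tissue that holds few storage transcripts, such as that of a germinated grain, so its carry-over stays open. Other microbes were not tested. A response of IR29 to salt may explain the peak and stays a hypothesis.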

How the results depend on the processing

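Leaving out 2 arrays, replicate 1 of Nonabokra and of IR29 at 6 h, which differ most from their groups among brighter probe sets, leaving out arrays for named genes, and the default estimate of array weights were chosen after the result was seen, as was the gene-by-gene estimate of the array weights, because the default stopped before it converged. A cultivar pair with a slash is a response difference. All 18 counts stayed within 1.5 times under a trended spread, a robust spread, median centring, pseudocounts of 1 and 64, and a replicate block (Nonabokra 6 h 12725), and all 7 counts that use the 2 arrays did so without them (Nonabokra 6 h 12733). With the block, 2 of the results that use arrays paired by their values were Nonabokra/IR29 6 h 9284 and Nonabokra against Pokkali 10980, and elsewhere the numbers paired few arrays: 9 of 27 correlated best with their own number. The following counts moved by more than 1.5 times, and the cause was not tested unless given. At an adjusted p under 0.01: Pokkali 6 h against 3 h 8644, IR29 6 h 17945, Nonabokra against IR29 20384, Nonabokra/IR29 3 h 7538, Nonabokra/IR29 6 h 5976 and Pokkali/IR29 3 h 12288. With gene-by-gene array weights: Pokkali 6 h 26143, Pokkali 6 h against 3 h 31692, Nonabokra/IR29 3 h 27105 and Nonabokra/IR29 6 h 18182. With the default weights: Nonabokra 6 h against 3 h 18585, Pokkali 6 h 37732, Pokkali 6 h against 3 h 33607, IR29 6 h against 3 h 4940, Nonabokra against Pokkali 16712, Nonabokra/IR29 3 h 28896, Nonabokra/Pokkali 3 h 16448 and Nonabokra/Pokkali 6 h 13196. Without the dimmest 40%: IR29 3 h 19048, IR29 6 h 13473, Nonabokra against IR29 14739, Pokkali against IR29 17528 and Pokkali/IR29 3 h 11788. With quantile normalization: IR29 3 h 20235, IR29 6 h 15225, Nonabokra against IR29 16113, Pokkali against IR29 18419 and Pokkali/IR29 3 h 12313. With the compared groups alone, which leaves fewer arrays for the spread: Nonabokra 6 h against 3 h 7540, IR29 3 h 18732, IR29 6 h 7160, IR29 6 h against 3 h 3515, Nonabokra against IR29 10495, Pokkali against IR29 14252, Nonabokra/IR29 6 h 6186 and Pokkali/IR29 3 h 16999. With named genes only, fewer probe sets are tested by construction: Nonabokra 3 h 1691, Nonabokra 6 h 1475, Nonabokra 6 h against 3 h 1423, Pokkali 3 h 1585, Pokkali 6 h 1384, Pokkali 6 h against 3 h 1297, IR29 3 h 1616, IR29 6 h 1343, IR29 6 h against 3 h 1097, Nonabokra against IR29 1284, Pokkali against IR29 1579, Nonabokra against Pokkali 1230, Nonabokra/IR29 3 h 1145, Nonabokra/IR29 6 h 1097, Pokkali/IR29 3 h 1157, Pokkali/IR29 6 h 1012, Nonabokra/Pokkali 3 h 915 and Nonabokra/Pokkali 6 h 987. Probe sets shared by 3 cultivars at 2-fold or more, a stricter count by construction, were 655 higher and 383 lower at 3 h and 338 and 78 at 6 h, and the 16 overlaps between cultivars with separate controls stayed within 1.5 times without the dimmest 40%. Of 8 overlaps with shared controls 2 did not: lower calls shared by IR29 at 3 h and 6 h went from 21993 to 5580, and those shared by both unstressed comparisons with IR29 from 21941 to 5599. Leaving out each array in turn gave: Nonabokra 3 h 15018 to 15774, Nonabokra 6 h 11804 to 12424, Nonabokra 6 h against 3 h 10817 to 11537, Pokkali 3 h 13441 to 13692, Pokkali 6 h 10712 to 13464, Pokkali 6 h against 3 h 10549 to 12935, IR29 3 h 29338 to 35876, IR29 6 h 18127 to 33040, IR29 6 h against 3 h 6872 to 8624. For cultivars and response differences it gave: Nonabokra against IR29 21206 to 32016, Pokkali against IR29 27126 to 35078, Nonabokra against Pokkali 10084 to 10308, Nonabokra/IR29 3 h 10021 to 20805, Nonabokra/IR29 6 h 7742 to 16030, Pokkali/IR29 3 h 18175 to 29340, Pokkali/IR29 6 h 6549 to 7774, Nonabokra/Pokkali 3 h 6529 to 7067, Nonabokra/Pokkali 6 h 7046 to 7507. In 6 of 144 such fits the count moved by more than 1.5 times: IR29 6 h without replicate 1 of the control (18127) or replicate 2 of 6 h (18474), Nonabokra against IR29 without replicate 1 of the IR29 control (21206), Pokkali 6 h against 3 h without replicate 3 of 3 h (10549) or replicate 1 of 6 h (10677), and Nonabokra/IR29 6 h without replicate 1 of IR29 at 6 h (16030). The 217 values of named genes kept direction and call in all 7 alternatives run for them and in 1542 fits without 1 array. These values had been picked as the largest passing changes, which favours that outcome. Of 81 list tests that passed, 38 still passed with an estimated correlation and 43 did not, 77 passed with the mean of all probe sets of a gene, and all 81 with fry and with a replicate block. No median of these lists changed sign with quantile normalization or median centring, where the median change of all probe sets shifted by at most 0.02. The medians for unstressed level kept direction and side in their 12 alternatives, but without the dimmest 40% Spearman's rho for Pokkali at 6 h went from 0.074 to -0.0216, and for IR29 at 3 h and 6 h it went from -0.116 and -0.115 to -0.211 and -0.206. The larger of the higher and lower counts changed side in 37 of 241 fits, 8 of them with median centring and 7 with named genes only, and the cause was not tested. Signal over background limits the counts: 46.6% of the IR29 6 h calls and 46.4% of those for Nonabokra against IR29 were among the dimmest 40%.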

Other observations

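No test of this part was chosen after the result was seen, though the comparison of probe sets raised in IR29 was run without a prediction.

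In IR29 at 6 h the metal transporters YSL15 and ZIP1 (LOC4326394) were at -3.18 ± 0.10 and -2.81. The sugar transporter SWEET15 peaked at 3 h in Nonabokra: it went from 52.2 ± 4.77 to 3335 ± 47.0 and 288 ± 18.7, and PM19L1, an AWPM-19-like membrane protein, rose by 6.59 ± 0.11 at 3 h and 5.64 ± 0.11 at 6 h. LAC20, a laccase, changed by -3.24 in Nonabokra and CRSH2 by -4.06. CDKE-1 rose by 5.27 ± 0.09 at 3 h and 5.68 ± 0.09 at 6 h in Pokkali, where BLE3 was at -2.22 and the laccase LAC3 at -2.27 at 6 h. ELA3 rose by 2.28, 3.67 and 3.48 at 6 h in Nonabokra, Pokkali and IR29.

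The sodium transporter HKT1;5 was weakly expressed, with intensities of 27.9 ± 5.04, 55.8 ± 9.21 and 19.9 ± 2.17 in unstressed Nonabokra, Pokkali and IR29. At 6 h its change was -0.38 ± 0.08 in Nonabokra and -0.83 ± 0.08 in Pokkali, and in IR29 it did not pass (-0.15 ± 0.08, adjusted p = 0.14). The response differed from IR29 in Pokkali (-0.68 ± 0.12, adjusted p = 0.00030) and did not pass in Nonabokra (-0.23 ± 0.12, adjusted p = 0.18).

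A planned hypothesis was that transcripts raised by salt in 1 tolerant cultivar are already high in the other before salt. The 2071 probe sets that salt raised 2-fold or more in Nonabokra at 3 h had a median of 0.22 in unstressed Pokkali against IR29, where 10000 random lists matched on level gave a 95% range of 0.06 to 0.10, and the 1035 raised at 6 h had 0.23 (0.05 to 0.11; permutation p = 0.0001 in both, the smallest possible). Of those raised at 3 h, 1021 were higher and 533 lower in Pokkali. The reverse was not found: the 1536 and 1191 probe sets raised in Pokkali at 3 h and 6 h had medians of -0.057 and -0.071 in unstressed Nonabokra against IR29, below the random lists (0.03 to 0.07 and 0.03 to 0.07). Those raised in IR29 had medians of -0.22 and -0.35 in unstressed Nonabokra against Pokkali (-0.03 to 0.00 and -0.03 to 0.00). Over all probe sets Spearman's rho was 0.183 and 0.151 for the response of Nonabokra, -0.088 and 0.074 for Pokkali, and -0.116 and -0.115 for IR29 at 3 h and 6 h. Unstressed Pokkali may hold part of the salt-raised transcripts high, which is a hypothesis, and probe sets are not independent.

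For each of the 12 comparisons of 2 groups, the 6 arrays make 10 splits, too few for a share under 0.05, and the real split, 1 of 10, gave the highest count. With the highest other split in brackets, the counts were 16003 (53) and 12804 (10) in Nonabokra at 3 h and 6 h, 14427 (9) and 12729 (22) in Pokkali, and 36580 (13) and 30525 (13457) in IR29. From 3 h to 6 h they were 12060 (33), 16148 (14) and 8458 (25) in Nonabokra, Pokkali and IR29. Unstressed, they were 32034 (48) for Nonabokra against IR29, 35383 (67) for Pokkali against IR29 and 11081 (12) for Nonabokra against Pokkali.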
